A study of Rattus norvegicus with 6 samples.

How the data were processed

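Bulk RNA sequencing was available for 6 sciatic nerve samples of female Sprague-Dawley rats aged 8 weeks, taken on day 4. Per the labels' protocols, the nerve had retracted to leave a gap of about 6 mm, and the ES group received electrical stimulation for 1 h at once, while the control group received none. The proximal and distal nerve ends were then each sutured 2 mm deep into a 10 mm silicone tube. RNA was isolated with TRIzol and libraries were made with a NEBNext Ultra kit, per the labels' protocols. The group and the replicate number of each sample were read from its title, which gave 3 control and 3 ES samples. The labels do not say whether the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

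The authors deposited a table of whole-number read counts per gene, with 1 column per library and no pooling. They also deposited a table of FPKM values for the same libraries and a table of FPKM group means. Each deposited FPKM value equalled the count divided by the gene length of the table and by 1 depth constant per library. That constant differed from the column total of counts by −2.30% to 1.83%. From the total scaled by a TMM factor over all genes it differed by −0.06% to 0.39%. Fits on the FPKM values therefore carry nearly the same scaling as the main test. The group means matched the means of the FPKM columns and were used only for this check. The aligner, the counting tool and its treatment of strand are not given in the sources used here. The submitters' processing notes name the build rn7. The deposited tables, however, hold 6890 genes with clone names starting AABR07, and their genes on chromosome 1 reach position 282724300, which resemble the earlier rat build Rnor_6.0. The build of the printed coordinates is therefore not settled, and they are given as the deposited tables state them.

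The count table held 33713 genes, of which 20925 had a count in any library, and 2 of its lines were empty. It included 830 loci with an identifier and coordinates but no gene name, which took 0.723% to 0.840% of the counts of a library. The design written before the data were examined left out lines that name no gene. Keeping these loci departed from that wording. Of the 558 tested, 0 were called by edgeR, while DESeq2 called 7, and an alternative without them is given with the other alternatives. Library totals ran from 14962319 to 17119144 counts. Counts of 2 libraries of the same group differed far beyond sampling noise, with a chi-square per gene of 10.6 to 18.3, so every library counted as 1 replicate.

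The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust dispersion estimates, after filterByExpr and TMM normalization, two-sided. It kept 14828 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold cutoff. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled by library size and TMM factor. A total of 35 gene lists were fixed at the same time as the design, as were the groups, the tests, the naming rule and all alternatives not named below as later ones. Of their 750 memberships, 721 matched a gene of the table by symbol or by an older symbol from a RefSeq gene table of another rat assembly (GRCr8), used for names only. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists tested. The list of nuclear-retained long RNAs had too few matched members and was not tested. Camera with an estimated correlation and fry were alternatives.

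Genes are named by a rule in 3 parts. The first takes, among called protein-coding genes with a symbol, a mean of at least 1 CPM and no overlap between the groups, the 12 largest rises and the 12 largest falls. Another part is a fixed panel, of which Jun, Gdnf, Shh, Sox2, Ngfr, Gap43, Bdnf, Mbp, Egr2, Ccl2, Il1b, Cd68 and Mki67 are reported; some results of the panel are left out of the text. The last takes up to 4 members with the lowest unadjusted p from each list. Genes named outside this rule are said to have been chosen after their values were seen.

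The scripts were tested on simulated counts for the ES and control comparison, drawn from the real means, dispersions and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. In 14682 simulated genes, edgeR recovered 75 of the 2-fold and 90 of the 4-fold changes and called 13 unchanged genes. DESeq2 1.42.0 recovered 81 and 90 of them and called 24 unchanged genes. Without any simulated change, edgeR called 1 gene and DESeq2 called 19. With the simulated changes, edgeR called 178 genes, edgeR with non-robust dispersions 172 and limma-voom 171. In the real data these tests called 25, 2 and 2 genes. The simulation did not reproduce this gap, so it cannot measure the error of the 25 calls. Lists of 15 simulated genes, drawn independently of one another among 14658 genes run for this comparison, were tested with limma. For members raised 1.5-fold the value was 2.73e-19 by camera with the preset correlation, 0.00135 with an estimated one and 0.00011 by fry. For unchanged members it was 0.899 by camera. Independent draws lack the correlation between members that the real lists held, estimated at 0.744 for adipocyte markers and 0.613 for the fibroblast list. This check therefore cannot measure the error of camera at the preset correlation in these data.

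The alternatives were other normalizations and filters, DESeq2, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a filter at an FPKM of 1 and on log2(FPKM + 1) without it, a model with the replicate number as a block, each library left out in turn, non-robust dispersions and stricter thresholds. The alternatives chosen after seeing the data were the adipocyte score as a covariate, the omission of mitochondrially encoded genes and the omission of the unnamed loci. No base-level data were analysed here.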

Results

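The transcriptome of injured rat sciatic nerve was measured on day 4 in 3 samples that had received electrical stimulation for 1 h at the time of injury (ES) and in 3 that had not (control). Control libraries held 16232192, 15220907 and 15595618 counts and ES libraries 16853717, 17119144 and 14962319 counts. The biological coefficient of variation was 0.160. The first principal component of log2 CPM held 34.1% of the variance. Control libraries lay at −33.5, −9.46 and −19.2 on it, and ES libraries at 38.3, 13.02 and 10.9.

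The design asks which genes differ between stimulated and unstimulated injured nerve. Gstm3, a glutathione S-transferase of the mu class, was nearly absent from control nerve (0.428 ± 0.146 CPM, SD, n = 3) and present in all 3 ES libraries (15.7 ± 2.55 CPM, SD, n = 3). Mcoln3, which encodes an endolysosomal cation channel, rose from 11.6 ± 0.0967 to 24.9 ± 1.67 CPM. Slc7a10, an amino acid transporter made by fat cells, fell, at 16.6 ± 4.14 CPM in control and 1.32 ± 0.753 CPM in ES. The clock genes Dbp and Nr1d1 also fell, by 1.13 and 0.81 on the log2 scale. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 25 of 14828 genes, 5 higher and 20 lower in ES.

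The 5 genes called higher were Gstm3, Mcoln3, Lilrb4, Nqo1 and Myo1f. Gstm3 (ENSRNOG00000049743, chromosome 2, 210685197 to 210688272) had a log2 fold change of 5.18 ± 0.26 (SE), 36.3-fold, with an edgeR adjusted p of 2.1e-05. Its control libraries held 5, 9 and 6 counts and its ES libraries 314, 246 and 210. Mu-class transferases are similar in sequence, so reads could be shared between Gstm3 and its relatives, and its level is uncertain to that extent. Mcoln3 (ENSRNOG00000015024, chromosome 2, 251983339 to 252007560) had a log2 fold change of 1.10 ± 0.11 (SE), with an edgeR adjusted p of 0.0064. Lilrb4, an inhibitory receptor of myeloid cells that belongs to a gene family with similar members, rose by 0.91 ± 0.13 (SE) on the log2 scale. Nqo1, a quinone reductase, rose from 22.1 ± 0.687 to 36.1 ± 4.57 CPM, and Myo1f, a myosin of white blood cells, from 50.6 ± 4.36 to 75.2 ± 6.10 CPM. The edgeR adjusted p of these 3 genes lay between 0.037 and 0.049.

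Among the genes called lower, Oxtr, the oxytocin receptor, had the largest fall (log2 fold change −5.61 ± 0.67, SE), with 44, 85 and 123 counts in the control libraries and 0, 3 and 2 in the ES libraries. Its fold therefore rests on 5 counts in the ES group. Slc7a10 was 12.7-fold lower, Sucnr1, the succinate receptor, 9.26-fold lower, and Mst1, which encodes macrophage-stimulating protein, 7.6-fold lower. Oxtr, Slc7a10, Sucnr1 and Mst1 were each lowest in ES 1, the library with the lowest mean log2 CPM of the adipocyte list (2.76). In control, Slc7a10, Sucnr1 and Mst1 were highest in control 1, where that mean was highest (6.53), while Oxtr was lowest there. With this mean, the adipocyte score, as a covariate chosen after seeing the data, edgeR called none of these genes. The score did not overlap between the groups, so that fit cannot tell fat content from stimulation. Whether these falls follow the fat content of the libraries stays open. Rasd1, the extracellular matrix gene Papln, the synaptotagmin Syt15 and Tnfrsf11b, which encodes osteoprotegerin, had log2 fold changes of −1.45, −1.42, −1.39 and −1.31. Dbp was at 57.7 ± 8.12 CPM in control and 26.3 ± 4.78 CPM in ES, Nr1d1 at 51.2 ± 5.24 and 29.2 ± 2.13 CPM, and Gpr83, a G protein-coupled receptor, at 40.1 ± 3.32 and 18.8 ± 4.49 CPM (SD, n = 3). Ntrk2, the receptor for brain-derived neurotrophic factor, was at 41.0 ± 3.77 CPM in control and 24.9 ± 2.32 CPM in ES. The edgeR adjusted p of these 12 genes was 0.037 or 0.043. The other 8 genes called lower had log2 fold changes between −2.38 and −0.51. They were Kdr, Myh11 and Srebf1, members of lists given below, and Rpl30, Bcam, Csad, Atp2b4 and LOC691485, which are outside the naming rule and are named after their values were seen. Rpl30 has pseudogenes that could share its reads.

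**Figure D1:**
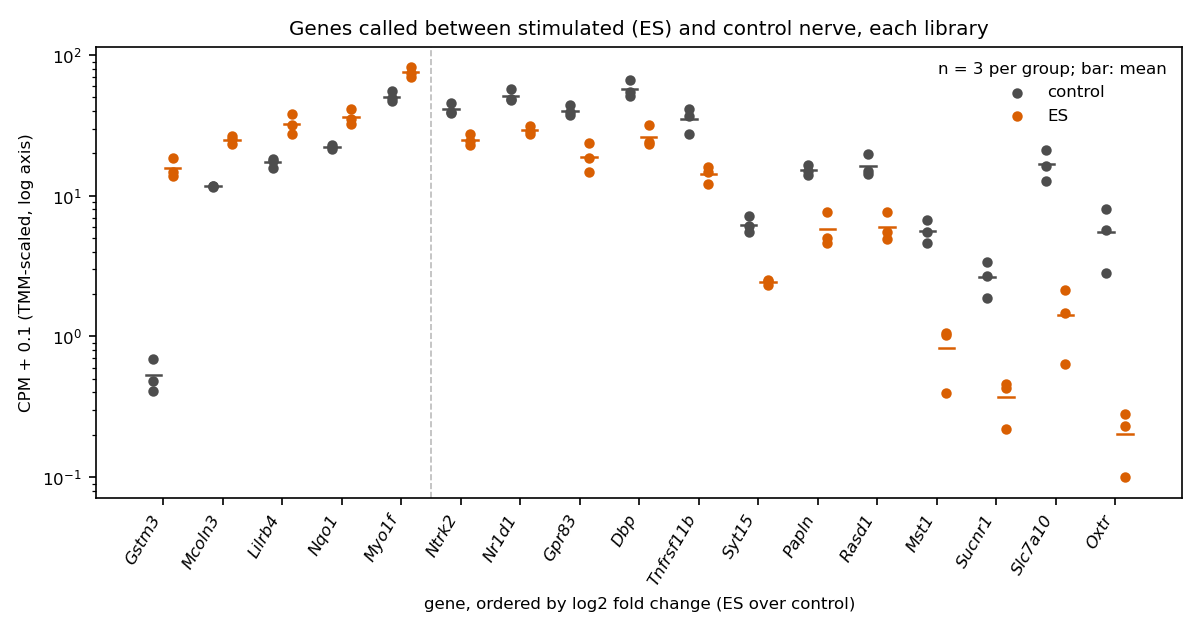
TMM-scaled CPM plus 0.1 (log axis) of the 17 named genes with the largest called changes, in each of 3 control (grey) and 3 ES (orange) libraries, with a bar at each group mean. The groups do not overlap for any of these genes; Gstm3 lies at 0.308 to 0.590 CPM in control and 13.8 to 18.6 CPM in ES.

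All 25 called genes had no overlap between the groups. Of all tested genes, 15.8% had none, against 10% by chance. At an unadjusted p under 0.05, edgeR gave 1475 genes, 594 higher and 881 lower, where 741 would be expected by chance. The count of 25 depended on the test and on single libraries: DESeq2 called 309 genes, limma-voom 2 and edgeR with non-robust dispersions 2, and edgeR called 5 genes without control 1, 152 without control 2, 2 without control 3 and 41 without ES 3. Without ES 1, 13 genes were called lower, and without ES 3, 22 were called higher. Gstm3 was called by all of these, and Mcoln3 by all but the fit without control 3 (edgeR adjusted p = 0.072; range 1.16e-09 to 0.128 over all alternatives).

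Among the reported genes of the fixed nerve repair panel, edgeR called 0 over all genes, and Cd68 and Mbp had an unadjusted p under 0.05. Jun, the transcription factor of repair Schwann cells, was at 810 ± 102 CPM in control and 876 ± 61.3 CPM in ES. Log2 fold changes were −0.09 ± 0.13 (SE) for Gdnf, −0.22 ± 0.38 for Shh, 0.07 ± 0.09 for Sox2, 0.21 ± 0.12 for Ngfr, 0.20 ± 0.32 for Bdnf and −0.07 ± 0.16 for Gap43. The proliferation marker Mki67 had a log2 fold change of −0.03 ± 0.11, the myelin regulator Egr2 one of 0.22 ± 0.16 and the chemokine gene Ccl2 one of −0.16 ± 0.09. The macrophage marker Cd68 was at 98.0 ± 3.68 CPM in control and 149 ± 27.1 CPM in ES (edgeR adjusted p = 0.116), and Mbp, which encodes myelin basic protein, had a log2 fold change of 0.31 ± 0.09 (edgeR adjusted p = 0.266). DESeq2 called Cd68 and Mbp, and edgeR called Cd68 without a filter on low counts (adjusted p = 0.0388) and without ES 3 (adjusted p = 0.00959; range 0.000312 to 0.804 over the alternatives). Il1b was at 37.7 CPM in ES 2 and at 0.983 to 2.96 CPM in the other libraries.

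Of the 34 tested gene lists, camera with a preset correlation called 15, 9 higher and 6 lower in ES, after Benjamini-Hochberg adjustment. With an estimated correlation it called 0, and 4 lists had an unadjusted p under 0.05; fry called 0 lists for a shift in 1 direction, with 8 at an unadjusted p under 0.05, and 7 for change in either direction. The preset correlation of 0.01 lies far below that estimated for several called lists, such as 0.744 for adipocyte markers. Its p-values are likely too small for such lists. In 6 of the 10 splits of the libraries into 3 and 3, camera at this setting called at least 15 lists. The number of called lists is therefore no evidence of a difference between the groups. Called lists below are given with both camera values, and higher or lower describes these libraries.

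Adipocyte markers were lower in ES, with a median log2 fold change of −2.04 over 14 members, 13 of them below 0 (camera adjusted p = 1.19e-28; adjusted p = 0.231 with an estimated correlation). No member was called over all genes by edgeR, and 2 were lower when adjusted over the list alone, Acsl1 and Gpd1, both enzymes of lipid metabolism. Acsl1 was at 226 ± 70.4 CPM in control and 61.2 ± 13.9 CPM in ES, and Gpd1 at 176 ± 18.9 and 35.4 ± 14.5 CPM. Adipoq, which encodes adiponectin, was at 140 to 266 CPM in the control libraries and at 6.28, 45.7 and 24.5 CPM in ES 1, ES 2 and ES 3. DESeq2 called 3 members of this list lower.

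**Figure D2:**
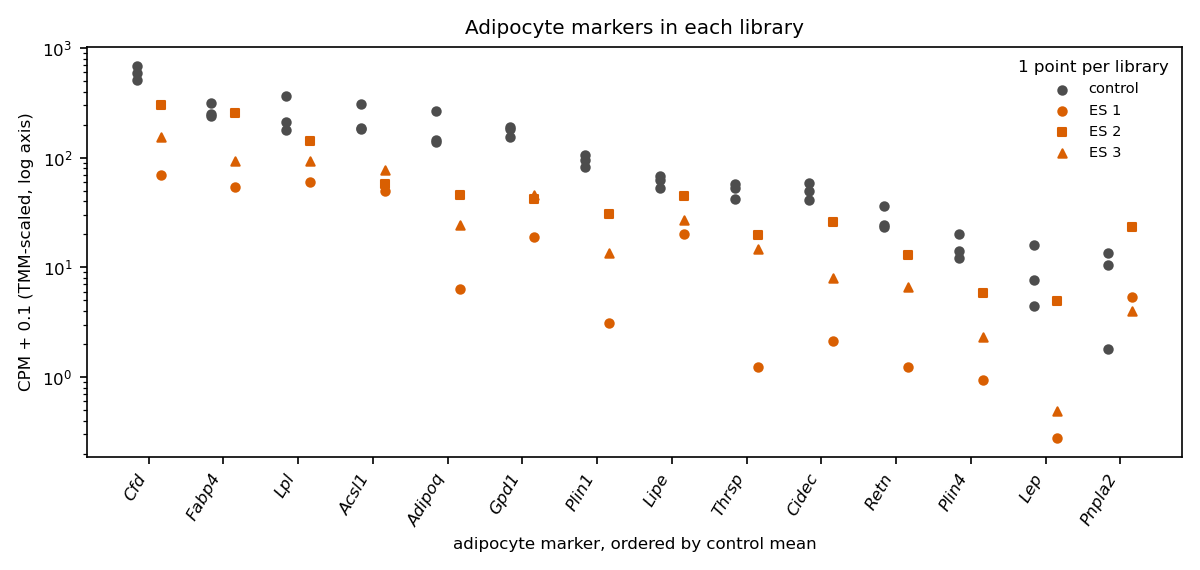
TMM-scaled CPM plus 0.1 (log axis) of the 14 tested adipocyte markers, 1 point per library, with 3 control libraries (grey) and each ES library by its own orange symbol. For 11 of the 14 markers, ES 1 is the lowest, ES 3 lies between and ES 2 is the highest of the ES libraries.

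Markers of vessels and connective tissue were lower in ES together with the adipocyte markers. The endothelial list had a median log2 fold change of −0.36, with 15 of 15 members below 0 (camera adjusted p = 3.97e-14; adjusted p = 0.211 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor, was called over all genes by edgeR, and 11 members were lower when adjusted over the list alone, including Tie1, Mmrn2 and Tek. Kdr fell from 54.9 ± 4.40 to 34.5 ± 2.49 CPM. The pericyte and smooth muscle list had a median of −0.58 over 13 members, 11 below 0 (camera adjusted p = 5.21e-12; adjusted p = 0.147 with an estimated correlation). Its member Myh11, the smooth muscle myosin heavy chain, fell by 0.71 ± 0.11 (SE) on the log2 scale and was called over all genes, and 10 members were lower when adjusted over the list alone, among them Lmod1, Cnn1 and Pdgfrb. The fibroblast and extracellular matrix list had a median of −0.35, with 22 of 23 members below 0 (camera adjusted p = 1.44e-11; adjusted p = 0.418 with an estimated correlation). No member was called over all genes, and 4 were lower when adjusted over the list alone: Dpp4, Fbn1, Fap and Col3a1. DESeq2 called 6 endothelial, 6 smooth muscle and 4 fibroblast members lower. With the adipocyte score as a covariate, chosen after seeing the data, the fibroblast list had a median of −0.20 and was no longer called by camera (adjusted p = 0.0791). The endothelial and smooth muscle lists were still called, with smaller medians of −0.21 and −0.28. The adipocyte score itself did not overlap between the groups, at 5.85 to 6.53 in control and 2.76 to 5.19 in ES. A fit with this covariate therefore cannot cleanly separate it from stimulation, here or for the lists below. Without control 1, the medians of the fibroblast and smooth muscle lists were −0.23 and −0.38, and both lists were still called.

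Macrophage and monocyte markers were higher in ES, with a median log2 fold change of 0.40 and 22 of 22 members above 0 (camera adjusted p = 1.40e-13; adjusted p = 0.290 with an estimated correlation). Their mean log2 CPM was highest in ES 2 (6.81), against 6.50 in ES 1, 6.42 in ES 3 and 6.08 to 6.27 in control. No member was called over all genes by edgeR, and 7 were higher when adjusted over the list alone, including Fcer1g, Tyrobp, Cd68 and Laptm5. Fcer1g and Tyrobp, signalling adaptors of myeloid receptors, had log2 fold changes of 0.39 ± 0.07 and 0.51 ± 0.10 (SE). DESeq2 called 6 members higher. The phagocytosis and lysosome list was higher with a median of 0.11 over 26 members (camera adjusted p = 0.000196; adjusted p = 0.418 with an estimated correlation). Adjusted over the list alone, 7 of its members were higher, among them Ctss, Msr1 and Gpnmb, and 1 was lower, the lipoprotein receptor gene Scarb1; DESeq2 called 5 higher and 1 lower. Msr1, a macrophage scavenger receptor, was at 26.1 ± 3.30 CPM in control and 48.2 ± 11.3 CPM in ES.

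Myelin and mature Schwann cell genes were higher in ES, with a median of 0.24 and 17 of 22 members above 0 (camera adjusted p = 7.81e-07; adjusted p = 0.572 with an estimated correlation). No member was called over all genes, and 6 were higher when adjusted over the list alone, including Drp2, S100b, Pmp2 and Fa2h; DESeq2 called 5 members higher. Drp2, a dystrophin-related protein of myelinating Schwann cells, was at 20.6 ± 1.67 CPM in control and 37.8 ± 8.97 CPM in ES. With the adipocyte score as a covariate this list had a median of 0.15 and was no longer called by camera (adjusted p = 0.0676). The heat shock and unfolded protein response list had a median of 0.24, with 17 of 19 members above 0 (camera adjusted p = 3.22e-06; adjusted p = 0.418 with an estimated correlation). Its members Dnajb1, Ddit3, Hsph1 and Atf4 were higher when adjusted over the list alone, with log2 fold changes between 0.24 and 0.43. Over all genes edgeR called 0 members, with 9 higher at an unadjusted p under 0.05, and DESeq2 called Dnajb1. Without ES 2 the median of this list was 0.15, and the list was still called by camera.

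Lists of inflammatory genes were called, but the calls rested on single libraries. Chemokines and cytokines had a median of 0.22 over 30 members (camera adjusted p = 0.0238; adjusted p = 0.674 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone by edgeR; 4 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher and 1 lower. Il18 had the lowest p of that list, at 7.62 ± 1.59 CPM in control and 12.6 ± 0.961 CPM in ES, and Cxcl12 stood at 131 ± 22.7 and 69.7 ± 15.9 CPM. The pro-inflammatory macrophage list had a median of 0.37 over 11 members (camera adjusted p = 0.0384; adjusted p = 0.674 with an estimated correlation), with 0 members called by edgeR over all genes or adjusted over the list alone, 2 higher at an unadjusted p under 0.05, and 0 called by DESeq2. Matrix proteases and inhibitors had a median of 0.17 over 21 members (camera adjusted p = 0.0238; adjusted p = 0.674 with an estimated correlation), with Plat, tissue plasminogen activator, higher and Adamts5, an aggrecan-cleaving protease, lower when adjusted over the list alone and 0 called over all genes; DESeq2 called 2 higher. Without ES 2, camera gave these 3 lists adjusted p-values of 0.705, 0.530 and 0.609, and without control 2, values of 0.317, 0.584 and 0.107. Their medians without ES 2 were 0.07, 0.14 and −0.03. The pro-inflammatory list also lost its camera call without a filter on low counts (adjusted p = 0.0858). Without ES 3 the chemokine median was 0.44 and that of matrix proteases 0.26, and the chemokine median was 0.37 without control 1 and 0.54 without control 3. It was 0.71 without a filter on low counts and 0.55 with the adipocyte score as a covariate, and that of matrix proteases 0.36 with this covariate.

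ES 2 also stood apart in markers of blood. Hbb, a beta globin gene, was at 1140 CPM in ES 2 and at 54.1 to 134 CPM in the other libraries. S100a9, an abundant neutrophil transcript, was at 91.2 CPM in ES 2, 4.39 CPM in ES 1 and 3.15 CPM in ES 3. In control it was at 0.852 to 1.23 CPM, so ES 1 and ES 3 also lay above control for this gene. Neither the erythrocyte list (median 1.54, camera adjusted p = 0.0899) nor the neutrophil list (median 1.10, camera adjusted p = 0.0742) was called. Mpo, the myeloperoxidase gene of the neutrophil list, went the other way, at 7.98 ± 2.57 CPM in control and 0.544 ± 0.425 CPM in ES (edgeR adjusted p = 0.091), and was lower when adjusted over the list alone. DESeq2 called Mpo lower (adjusted p = 7.33e-13) and Csf3r, a neutrophil growth factor receptor, higher. The erythrocyte list was called higher by camera without ES 1 (adjusted p = 0.000398) or ES 3 (adjusted p = 0.000171) and lower without ES 2 (adjusted p = 0.00679). The neutrophil list was called higher by camera without ES 1 (adjusted p = 0.00255), without ES 3 (adjusted p = 0.000656) or without a filter on low counts (adjusted p = 0.0201), and its median was 0.14 without ES 2 (adjusted p = 0.453).

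Metabolic lists moved by small amounts, as did the ribosomal protein and mitochondrially encoded lists, which were fixed as measures of RNA quality. Whether RNA quality differed between the groups was not tested further. Cholesterol and fatty acid synthesis was lower by its mean of −0.19, while its median over 27 members was −0.04 (camera adjusted p = 0.00935; adjusted p = 0.418 with an estimated correlation). Srebf1, a transcription factor of lipid synthesis, fell from 129 ± 7.64 to 82.5 ± 11.3 CPM, and was the 1 member called over all genes by edgeR and adjusted over the list alone. DESeq2 called 4 members lower, Srebf1, Insig1, Fasn and Scd. Scd, which is also abundant in fat, was at 202 ± 145 CPM in control and 34.3 ± 10.1 CPM in ES. Hypoxia and glycolysis was higher, with a median of 0.16 over 23 members (camera adjusted p = 0.00587; adjusted p = 0.674 with an estimated correlation), and 0 members were called by edgeR over all genes or adjusted over the list alone, with 5 higher and 1 lower at an unadjusted p under 0.05 and 1 called higher by DESeq2. The examples with the lowest p were Ldha, Pgam1, Aldoa and Eno1, with log2 fold changes of 0.38, 0.23, 0.24 and 0.26. Cytosolic ribosomal proteins had a median of 0.10 with 24 of 25 members above 0 (camera adjusted p = 0.00935; adjusted p = 0.674 with an estimated correlation), and mitochondrially encoded transcripts a median of −0.12 with 13 of 13 below 0 (camera adjusted p = 0.0269; adjusted p = 0.674 with an estimated correlation). Both had 0 members called by edgeR over all genes or adjusted over the list alone, and 0 by DESeq2. At an unadjusted p under 0.05 the ribosomal list had 0 members and the mitochondrial list 1. Rpl30, a ribosomal protein gene outside this list, was called lower by edgeR, with a log2 fold change of −0.72 (adjusted p = 0.0366). Single libraries ended the calls of all 4 of these lists. Without ES 2, camera gave adjusted p = 0.116 for cholesterol synthesis, 0.0991 for hypoxia and glycolysis and 0.175 for ribosomal proteins; without control 2, 0.0918 for cholesterol synthesis, 0.0817 for ribosomal proteins and 0.107 for mitochondrial transcripts; without control 1, 0.0789 for ribosomal proteins and 0.569 for mitochondrial transcripts; and without ES 1, 0.0739 for mitochondrial transcripts. The hypoxia and glycolysis median was 0.27 without ES 3. The cholesterol median was −0.12 without control 1, −0.06 without control 3, −0.10 without ES 1 and −0.02 without ES 2. The ribosomal median was 0.06 without control 1 or without ES 2 and 0.15 without control 3. The mitochondrial median was 0.00 without control 1 and −0.22 without control 3. With the adipocyte score as a covariate, camera no longer called hypoxia and glycolysis (adjusted p = 0.0791), whose median of 0.13 stayed close to the reported one, or mitochondrial transcripts (adjusted p = 0.755), whose median was 0.00. The medians of cholesterol synthesis and ribosomal proteins were −0.17 and 0.15 with this covariate.

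The repair programme and the axon lists were among the 19 lists that camera did not call. The repair Schwann cell programme had a median of 0.09 over 22 members (camera adjusted p = 0.112), with Btc, a ligand of the epidermal growth factor receptor family, higher when adjusted over the list alone at 121 ± 15.8 CPM in control and 160 ± 11.9 CPM in ES; without control 2 camera called this list (adjusted p = 0.0136). Neurotrophic and growth factors had a median of −0.04 (camera adjusted p = 0.966) and axon degeneration machinery a median of 0.04 (camera adjusted p = 0.858), with 0 members called by edgeR over all genes or adjusted over the list alone. At an unadjusted p under 0.05 the neurotrophic list had 2 higher and 2 lower and the degeneration list 1 and 1, and DESeq2 called 0 and 1 member. The mean of the degeneration list, −0.12, and its test pointed lower, against its median. Axonal and neuronal transcripts had a median of 0.03 (camera adjusted p = 0.966) against a mean of −0.05; Stmn2 was lower, at 4.03 ± 1.32 CPM in control and 1.38 ± 0.436 CPM in ES, and the tubulin gene Tubb3 higher, at 27.9 ± 5.58 and 40.9 ± 5.41 CPM, when adjusted over the list alone. DESeq2 called Btc, Stmn2 and Tubb3. The medians of the neurotrophic, degeneration, axonal and cell cycle lists lay near 0 and turned sign when single libraries were left out, none of them with a camera call. Cell cycle genes had a median of 0.03 (camera adjusted p = 0.333) and immediate early genes 0.10 (camera adjusted p = 0.186), with 0 members called by edgeR over all genes or adjusted over the list alone, 0 by DESeq2, and 0 and 1 at an unadjusted p under 0.05. Without ES 2 the immediate early median was 0.05, and its test pointed lower without a call (camera adjusted p = 0.705).

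Medians of the other lists without a call were 0.07 for autophagy (camera adjusted p = 0.0563), 0.07 for interferon response (0.238), 0.09 for MHC class II and antigen presentation (0.186), 0.06 for the pro-repair macrophage state (0.966, with a mean of −0.08), −0.07 for complement (0.858) and 0.04 for oxidative phosphorylation (0.142). Ion channels and calcium handling had a median of −0.12 (camera adjusted p = 0.112), mast cell markers −0.30 (0.0899), lymphocyte markers 0.14 (0.378), perineurial and epithelial-like markers −0.17 (0.252) and skeletal muscle −0.04 (0.856, with a mean of 0.00). No member of these 11 lists was called by edgeR over all genes, and DESeq2 called Ctss, Gbp2 and Itpr1. Adjusted over the list alone, edgeR called Gbp2, an interferon-induced GTPase, higher in the interferon list, Ctss higher in the MHC class II list and Itpr1, a calcium release channel, lower among ion channels. Of the skeletal muscle list, Tnnt3 was lower, at 5.67 ± 0.356 CPM in control and 3.51 ± 0.478 CPM in ES, and Tnni1 higher, at 0.466 ± 0.127 and 1.21 ± 0.0733 CPM. Leaving out 1 library gave camera calls to several of these lists and to cell cycle genes. Without ES 2, camera called cell cycle (adjusted p = 0.027), interferon (0.030) and, lower, complement (0.00267). Without ES 3 it called autophagy (0.0159) and, lower, mast cell markers (0.0187), and without control 1 autophagy (0.0384), which was also called without a filter on low counts (0.0309). Without control 3 it called MHC class II and oxidative phosphorylation (both 0.0231), and without ES 1 MHC class II (0.00669). Leaving out 1 library also turned the sign of some of these medians without a camera call. Without control 2 the medians were −0.05 for MHC class II, −0.18 for lymphocyte markers and −0.03 for interferon response, and that of ion channels shrank to −0.03. The median of MHC class II was −0.13 without ES 3, that of the pro-repair state −0.05 without ES 2, that of skeletal muscle 0.03 without control 1, and that of complement 0.02 without control 3 or ES 1.

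**Figure D3:**
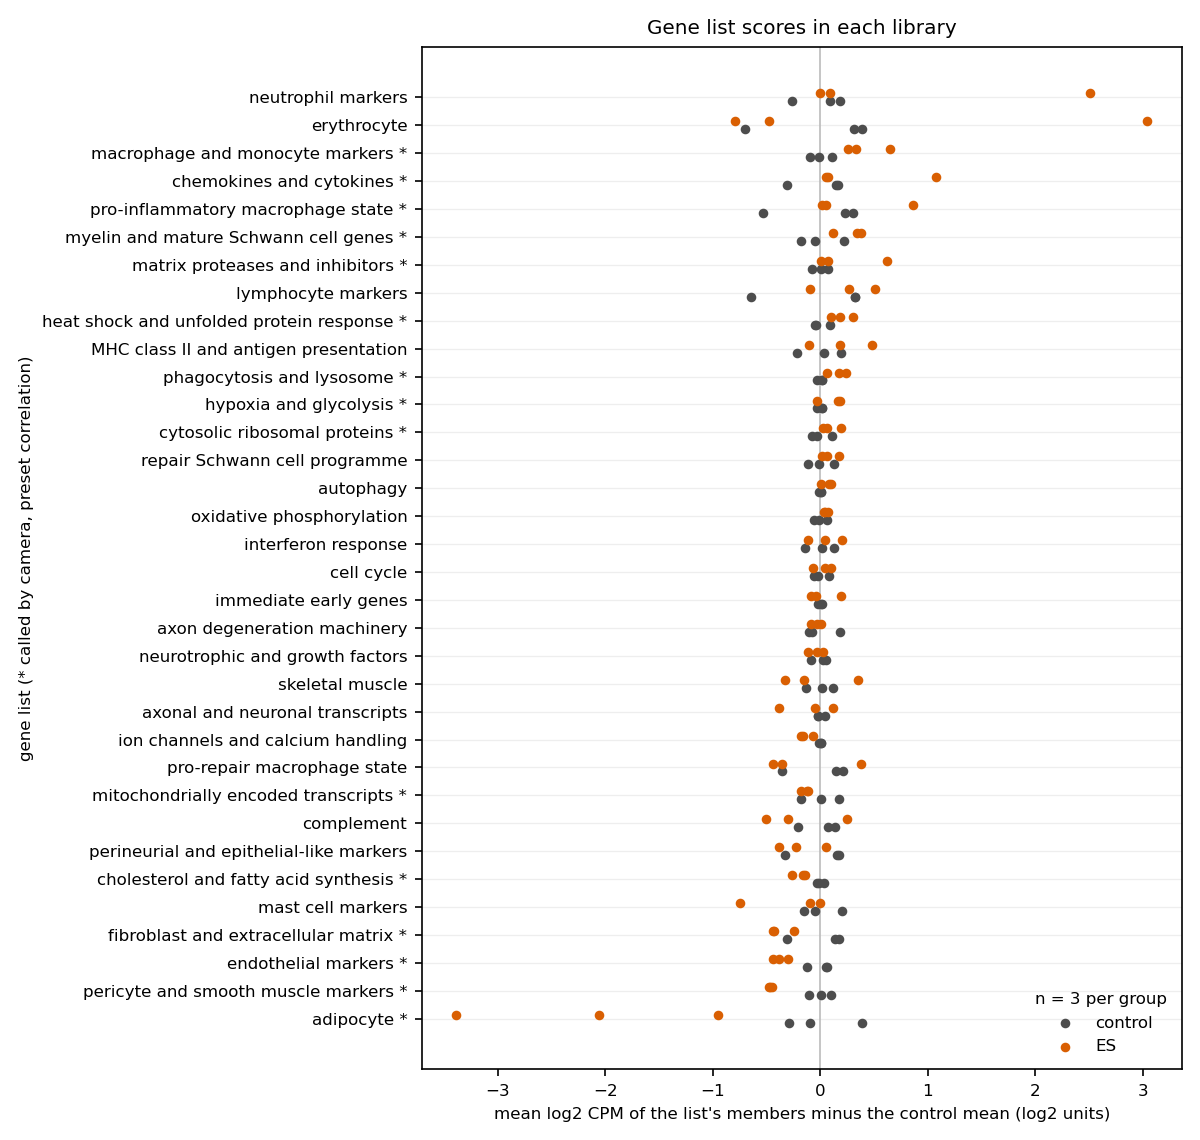
Mean log2 CPM of the members of each of the 34 tested gene lists in each library, minus the mean of the control libraries, for 3 control (grey) and 3 ES (orange) libraries; an asterisk marks the 15 lists that camera called with a preset correlation, 0 of which it called with an estimated one. The adipocyte scores of the ES libraries were the lowest, and ES 2 lay apart from the other libraries for the erythrocyte and neutrophil lists.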

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

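The alternatives with the adipocyte score as a covariate, without mitochondrial genes and without unnamed loci were chosen after seeing the data. The other normalizations, the stricter filter and the omission of mitochondrial genes or of unnamed loci called 25 to 35 genes, all 25 of the reported ones among them. More genes were called without a filter (35 higher, 97 lower, 132 in all) and by DESeq2 (99 higher, 210 lower, 309 in all), which included all 25. Fewer were called by limma-voom and by non-robust dispersions (each 2 higher, 0 lower, 2 in all), by limma on log2(FPKM + 1) (2 higher, 1 lower, 3 in all), on log2(FPKM + 0.1) (2 higher, 0 lower with 694 unadjusted, 2 in all) and on unfiltered log2(FPKM + 1) (3 higher, 1 lower, 4 in all). At unadjusted p under 0.05, limma-voom had 586 higher genes and the non-robust fit 623, against 594 in the reported test, and 928 and 914 lower genes, against 881; the cause was not tested. The adipocyte covariate left 11 higher, 1 lower and 12 in all, of which 1, Gstm3, was shared. A 2-fold threshold left 2 higher and 11 lower, 13 in all, and an adjusted p under 0.01 left 2 higher and 0 lower, 2 in all, since both thresholds are stricter.

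Leaving out 1 library gave 2 to 25 genes higher, 0 to 127 lower and 2 to 152 in all. The highest counts came without control 2 and the lowest without control 3; without control 1, 5 genes were called, and without ES 3, 41. Without ES 1, the genes called lower were 13. Gstm3 was called in 20 of 20 alternatives to the test, Mcoln3 in 18, Nr1d1 in 12 and each other gene in 8 to 11, and all 25 kept their sign. Single libraries ended most of these calls. Of the 25 genes, 8 stayed called without ES 1, 8 without ES 2, 13 without ES 3, 3 without control 1 and 1 without control 3. All 25 stayed called without control 2. For genes such as Myo1f, Sucnr1, Syt15, Bcam and Atp2b4, that was the 1 fit with a library left out that kept the call. Lists called numbered 10 to 19 when 1 library was left out, 0 with an estimated correlation, 0 by fry for direction and 7 by fry for mixed directions, and 14 to 19 otherwise. The erythrocyte median ran from −0.64 without ES 2 to 2.07 without ES 3. With the adipocyte covariate, the medians of the cell cycle (−0.085), complement (0.35) and perineurial (0.19) lists turned sign and the lists were called. It also brought camera calls, all higher, to the erythrocyte (adjusted p = 1.09e-21), neutrophil (3.68e-18), pro-repair macrophage (5.61e-09), immediate early (0.000111), MHC class II (0.000534) and lymphocyte (0.0117) lists. The adipocyte score did not overlap between the groups, so this covariate is hard to separate from stimulation. ES 2 had the highest adipocyte score of the ES libraries (5.19) and the highest erythrocyte (7.53) and neutrophil (3.89) scores. The erythrocyte and neutrophil calls therefore cannot be separated from that library, and the cause of the others was not tested. Sign changes without any call occurred for 42 gene values and 24 list values.

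With the replicate number as a block, 2 genes were higher, 9 lower and 11 in all, 7 of them among the 25, and 16 lists were called, the neutrophil list among them (camera adjusted p = 0.00912). Samples with the same number had correlations of −0.12, −0.13 and −0.04 of their deviations from the group means. No sample correlated best with its own number. The labels state no pairing and these correlations showed none, but with so few samples they cannot exclude one. At this depth Oxtr held 5 counts in the ES group, which limits its fold.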

Other observations

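The tests on tissue markers, of the clock genes against the adipocyte score and of inherited differences were chosen only after the result had been seen, as were the gene lists of the clock and of NRF2 targets. Beyond Dbp and Nr1d1, other clock genes that usually peak with them were lower in ES without passing edgeR's adjusted test: Nr1d2 had a log2 fold change of −0.58, Per3 of −0.49 and Tef of −0.27, each with no overlap between groups; DESeq2 called Nr1d2. Without Dbp and Nr1d1, 6 of the 8 genes of that list were below 0, and Per1 at 0.40 and Bhlhe41 at 0.10 were above it. Of the 5 genes of the opposite phase, 4 were above 0, Nfil3 at 0.39 and Arntl at 0.22 among them, and Clock stood at −0.02.

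Several genes that the transcription factor NRF2 is known to drive stood above control, as did the called Nqo1. Of 14 such genes without Nqo1, 12 had a log2 fold change above 0, some of them close to it, such as Prdx1 at 0.01 and Gsr at 0.10. None of the 14 was called by edgeR. Hmox1, heme oxygenase, was at 128, 92.0 and 105 CPM in control and 364, 220 and 122 CPM in ES, and Ftl1, a ferritin chain, had a log2 fold change of 0.31; edgeR called neither, and DESeq2 called Ftl1. The exceptions were Gclm at −0.01 and Me1 at −0.11.

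Model results were also computed for the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. In 1 of the 10 splits, the real one, edgeR called at least 25 genes, and the highest count of the other 9 splits was 2. For gene lists, 6 of the 10 splits called at least the 15 lists of the real split with camera at its preset correlation, and the highest of the others called 20.

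The first pattern was that adipocyte, vessel and fibroblast markers were lower in ES while macrophage markers were higher. Different amounts of adipose tissue in the libraries may underlie the adipocyte part: within groups, the adipocyte markers moved together, with a median correlation of 0.855 over pairs of markers. Markers of the same cell type would also move together if regulated jointly. The correlation therefore cannot separate regulation from a different amount of adipose tissue. Whether vessel and fibroblast markers came with that tissue stays open, since their within-group slope on the adipocyte score was 0.080 (95% interval −0.157 to 0.318), where 0.186 would account for the whole difference. Whether a smaller share of other tissue raised macrophage and Schwann cell transcripts alike stays open too, as the macrophage score minus the Schwann cell score differed between groups by 0.229 log2 units with a 95% interval of −0.270 to 0.728. The stimulation itself is confounded with any difference in dissection between the groups and was not tested apart from it.

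The next pattern was the lower level of clock genes. A different time of day at tissue collection is a candidate explanation, since the score of the opposite phase minus that in phase with Dbp, with Dbp and Nr1d1 left out, was higher in ES by 0.441 log2 units (95% interval 0.209 to 0.673). Whether in-phase transcripts were carried with adipose tissue stays open. With Dbp and Nr1d1 kept in, their within-group slope on the adipocyte score was 0.015 (95% interval −0.143 to 0.173). A slope of 0.194 would account for the whole difference, but that value is a ratio of observed group differences and is itself uncertain. The adipocyte score differed by −2.13 log2 units with a 95% interval of −4.16 to −0.106, so the slope cannot decide the question. An effect of the stimulation on the clock would give the same opposite shifts and cannot be told apart from collection time, which the labels used here do not give.

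The last pattern was Gstm3. Reads moved between members of the Gstm family stay open: the summed CPM of the other 7 Gstm genes differed by −16.6 (95% interval −36.2 to 3.11), while Gstm3 changed by 15.3 CPM. A rise of NRF2 target genes as a set may be part of it, since their score without Nqo1 was higher in ES by 0.224 log2 units (95% interval 0.029 to 0.418), a far smaller change than that of Gstm3. An inherited difference between animals that happens to follow the groups stays open as well: a gap of at least 3 log2 units between 3 libraries and the other 3 was found for 3 genes in the real split, Oxtr and an unnamed locus besides Gstm3, and in 1 of the other 9 splits, for LOC108348080. These genes were chosen after their values were seen. Intervals here come from the pooled spread of 3 and 3 libraries, and the smallest exact permutation p that this design allows is 0.1.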
